A study of Mus musculus with 8 samples.

How the data were processed

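RNA of 8 brain samples was hybridised to 1 Affymetrix 430B array each. The samples were neonatal cortex, neonatal cerebellum and whole brain at 15.5 and 13.5 dpc, each with a maternal duplication of proximal chromosome 7 and a paternal one of proximal chromosome 15, or the reverse. Per the labels' protocols, RNA was prepared with Trizol and a spin column kit, and biotinylated cRNA was made from 9 µg of total RNA. The deposited values are signal intensities on a linear scale, and per the submitters' processing notes they come from MAS5, whose version is not given in the sources used here. The values hold no detection calls and no log scale. The mean between the 2nd and the 98th percentile was 499.9 on each array, and no further normalization of the deposited intensity values was made. MAS5 summarises the perfect-match and mismatch probes of a probe set array by array, so low signals are noisy and may fall near 0. Depth has no meaning for arrays, and the number of arrays limits the precision.

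The 64 control probe sets were set aside and 22511 remained. Through the platform annotation and its gene identifiers, 14661 probe sets had 1 gene symbol, 245 had several and 7605 had none. A gene named for its size is given by the named probe set, from which its other probe sets may differ. Genes were named only from probe sets with 1 symbol, with symbols updated through the RefSeq gene table of GRCm38.p6, of which names, chromosomes, gene order and the placing of genes in windows of 10 Mb were used, and no positions are printed, since the files name no genome build. Signals were transformed as log2(signal + 58.5), where the pseudocount is the median over arrays of the 20th percentile, so that log2 differences understate the change of dim probe sets. A probe set was tested if its signal exceeded the array median on at least 2 of the 8 arrays, which kept 13221 (58.7%), with 6902 genes. A signal below its array's median was treated as not distinguishable from background. Where 1 side lay below it on every array, the difference of a probe set named for its size is also given as "at least N-fold" where it is printed singly, the geometric mean of the bright side over that of the larger of the dim signal and the array median, without pseudocount.

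Linear models with a term for each context and 1 for the duplication were fitted with limma 3.58.1 in R 4.3.3 (3 residual degrees of freedom) with empirical Bayes moderation. Contrasts gave paternal-7 minus maternal-7, cortex minus cerebellum, 15.5 minus 13.5 dpc, and the mean of the neonatal minus the mean of the embryonic contexts. A further model with separate duplication effects in neonatal and embryonic contexts tested their difference (2 residual degrees of freedom). P-values were adjusted by Benjamini-Hochberg over the tested probe sets with a threshold of 0.05, and ± after a log2 difference is its moderated standard error. The labels do not say whether samples came from separate animals, whether cortex and cerebellum came from the same ones, or whether RNA was pooled, so p-values measure only the spread between these arrays. Pair differences of cortex and cerebellum correlated at 0.242 across probe sets, and those of both embryonic ages at 0.217. The largest correlation between a neonatal and an embryonic context was 0.126.

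Gene lists (31, for imprinted genes, cell types, brain regions and pathways) were tested with camera at a preset correlation of 0.01, with the brightest probe set of each gene, where at least 3 genes were measured (26 lists). They were tested again with an estimated correlation, at which 0 lists were called in any contrast. That setting rests on the 3 residual degrees of freedom, so the small number of arrays alone can keep a list from being called, and it was not simulated. Of the lists left untested, markers of red blood cells and the sex-linked genes had 0 measured genes, and ribosomal protein, muscle and skin, and paternally expressed genes of proximal chromosome 7 had 2 each. Shares of chromosomes were tested with Fisher's exact test. Single pairs were compared as counts of probe sets that differed at least 2-fold, among those above the 75th percentile on either array.

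The genes named follow a rule fixed before the data were examined. It takes the listed imprinted genes of chromosomes 7 and 15, and for the duplications, where fewer than 5 probe sets were called, the 10 largest differences in each direction with 1 sign in 4 of 4 contexts, given as values. It takes the 12 largest called genes in each direction between contexts, with all arrays of one side above those of the other, with clone-type names limited to 3 in each direction, up to 4 members of each called list, the 5 largest differences in each direction within each context, and sex-linked genes. Probe sets added after their values were seen are said to be so. Alternatives fixed before the data were examined were quantile normalization, median centring, a floor of 1 without pseudocount, a pseudocount 4 times larger, no filter, a stricter filter at the 75th percentile, an intensity trend with robust moderation, leaving out probe sets shared between genes, models without the duplication or the context term, and leaving out each pair or array. The fits without both embryonic pairs, and the gene list tests without each pair, were chosen after seeing the data.

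The procedure was tested on simulated arrays with the real means and variances drawn from the distribution limma estimated, with 200 of 13221 probe sets changed in each of 5 simulations. For the duplications, effects of 1, 2 and 3 log2 units were recovered in 49.0%, 94.3% and 98.2% of cases, with 5.08% false calls. The 200 planted changes make the adjusted threshold less strict than in the real duplication contrast, and each simulated probe set had the same spread on all arrays. These shares may thus be too high for the real data, where a probe set at 4.42 ± 0.37 was not called (limma adjusted p = 0.0595). For cortex against cerebellum the shares were 9.25%, 82.7% and 95.5%, for 15.5 against 13.5 dpc 7.46%, 79.4% and 95.2%, and for neonatal against embryonic tissue 56.4%, 96.1% and 98.5%. For the difference of duplication effects they were 0%, 3.28% and 51.5%. In simulated independent genes, camera called 0% of 100 unshifted lists and 100% of 100 lists of 20 genes shifted by 0.5. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.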

Results

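Gene expression was measured in the brain of mice heterozygous for T9H, a reciprocal translocation between chromosomes 7 and 15. Each sample carried one of 2 complementary duplications. In the first, proximal chromosome 7 was duplicated from the mother and proximal chromosome 15 from the father, and in the second the parents were exchanged; they are called maternal-7 and paternal-7 here. Animals of this kind are used to find imprinted genes, which are expressed from the copy of one parent only. The contexts sampled were neonatal cortex, neonatal cerebellum, and whole brain at 15.5 and 13.5 days post coitum (dpc), with 1 array per duplication in each of the 4 contexts and 8 arrays in all. No context held a replicate of its own, so the error of every comparison came from how far the contexts or duplications departed from an additive model, and it does not separate animals from arrays. The trimmed mean signal was 499.9 on every array, and the array median lay between 229.8 and 286 signal units. Across probe sets, which are not independent replicates, both arrays of a context correlated at 0.953 in cortex, 0.949 in cerebellum, 0.891 at 15.5 dpc and 0.906 at 13.5 dpc. Of 22511 probe sets, 13221 were bright enough to be tested, and the number of arrays limited the precision.

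With the paternal duplication of chromosome 7, transcripts of Snhg14 were present in all 4 contexts, and with the maternal duplication they were at background. Snhg14 is a long noncoding RNA of chromosome 7 that hosts small nucleolar RNAs, is made from the paternal chromosome and runs antisense to Ube3a. One of its 3 probe sets, called A here, read 642 ± 219 (SD, n = 4 contexts) in paternal-7 arrays and 4.91 ± 2.58 (SD, n = 4) in maternal-7 arrays. The log2 difference was 3.41 ± 0.22 (SE, limma adjusted p = 0.0194), at least 2.47-fold because the maternal-7 signal lay below the array median. It was the only one of the 13221 probe sets past the threshold. At an unadjusted p under 0.05, limma counted 1147 probe sets against 661 expected by chance. Both other Snhg14 probe sets, B and C, were higher in 4 of 4 contexts without passing the test. Probe set B differed by 4.42 ± 0.37 (adjusted p = 0.0595, at least 5.54-fold) and C by 2.17 ± 0.23 (adjusted p = 0.162, at least 1.07-fold). For B the signals were 2372 against 0.262 in cortex, 1844 against 0.641 in cerebellum, 1197 against 3.67 at 15.5 dpc and 667 against 33.9 at 13.5 dpc. Without the cerebellum pair or without the 15.5 dpc pair limma called 0 probe sets, without the cortex pair 1, and without the 13.5 dpc pair 2, of which A was not one. The call was also lost with no filter on dim probe sets and with a floor of 1 in place of the pseudocount, while the strict filter called 4, all of them higher in paternal-7 arrays.

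**Figure D1:**
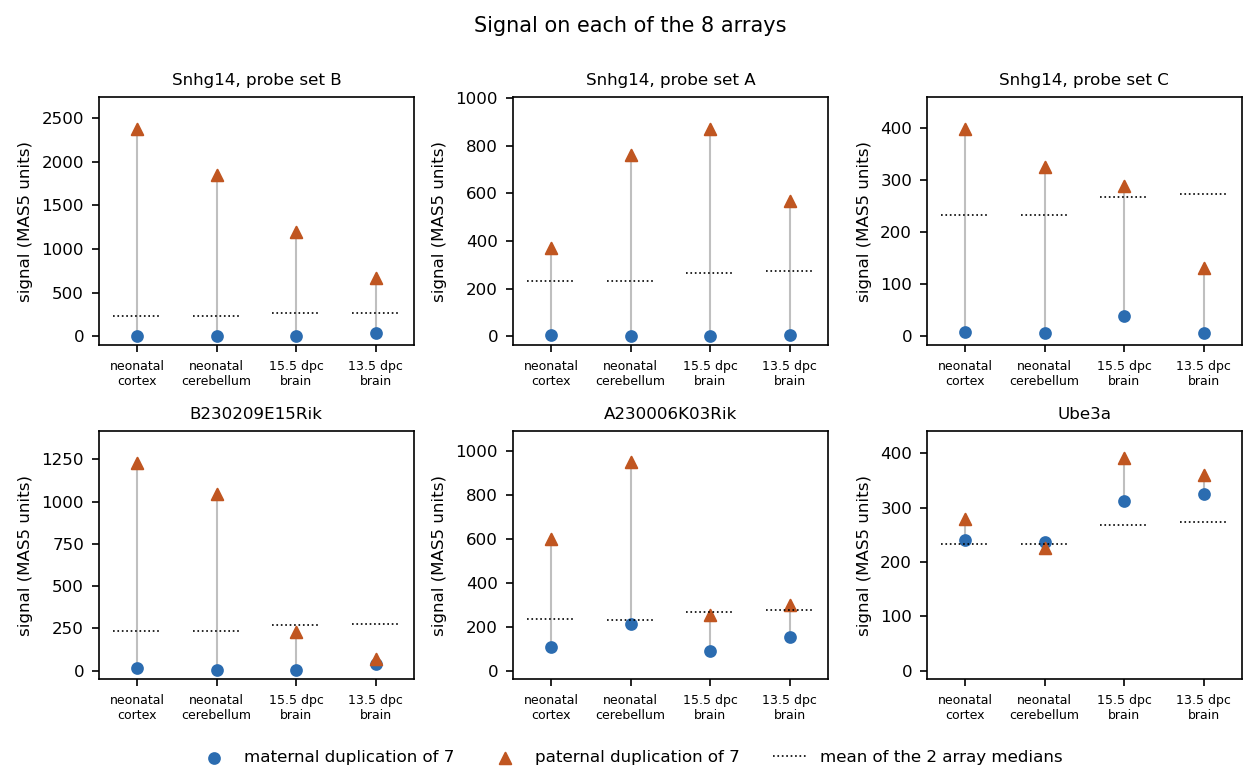
Signal in MAS5 units on each of the 8 arrays for the 3 probe sets of Snhg14 and for B230209E15Rik, A230006K03Rik and Ube3a, with circles for the maternal and triangles for the paternal duplication of chromosome 7 and a dotted line at the mean of the array medians of the context. The paternal-7 signals of Snhg14 probe set B run from 667 to 2372 while its maternal-7 signals stay at or below 33.9.

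Of the 4 other tested probe sets from Ube3a to Peg12, the stretch of chromosome 7 that holds Snhg14, 2 were higher in all 4 contexts without passing the test. B230209E15Rik and A230006K03Rik, clone-named transcripts of chromosome 7, lie beside each other on the far side of Ipw from Ube3a. They read 644 ± 578 against 14.8 ± 15.7 and 523 ± 321 against 140 ± 54.4 signal units (SD, n = 4 contexts), paternal-7 against maternal-7. Their log2 differences were 2.74 ± 0.61 and 1.43 ± 0.24, each higher in 4 of 4 contexts at an adjusted p of 0.532. Their maternal-7 signals lay below the array median, so these are differences of at least 1.54-fold and at least 1.84-fold. In a fit without both embryonic pairs, chosen after the data were seen, B230209E15Rik was called at 4.16 ± 0.16 (adjusted p = 0.00676). That exceeds its mean of 2.74 over all 4 contexts, so its embryonic differences were smaller. They may lie near background on both sides, and its count of 4 of 4 is one of signs, not of detection. Further probe sets, picked after their values were seen, also stood higher in paternal-7 arrays in 4 of 4 contexts. One that is listed for 2 genes of chromosome 7 differed by 4.66 ± 0.51 (adjusted p = 0.162, at least 7.46-fold), and one without a gene name here by 1.92 ± 0.22 (adjusted p = 0.171, at least 2.32-fold). Ube3a, a ubiquitin ligase made mainly from the maternal copy in neurons, differed by 0.13 ± 0.13 (adjusted p = 0.765) and was higher in 3 of 4 paternal-7 arrays. Its highest signal was 392 units, near the array medians. Another Ube3a probe set, below the median on every array and not tested, stood at -0.48 ± 0.71 (SD over 4 contexts). It was higher in 1 of 4 paternal-7 arrays, so Ube3a was barely measured here. Ipw, a paternally expressed noncoding RNA, differed by 0.32 ± 0.32 (adjusted p = 0.772), and by -0.10 without the 13.5 dpc pair.

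**Figure D2:**
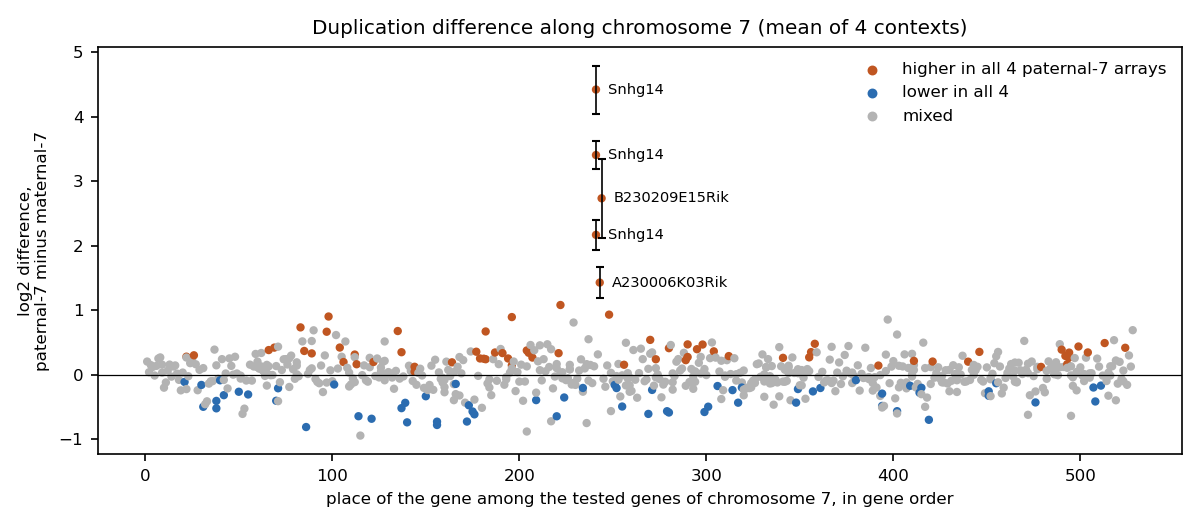
Log2 difference between paternal-7 and maternal-7 arrays, averaged over 4 contexts, for each tested probe set of chromosome 7, placed by gene order (horizontal axis, no unit), in orange where all 4 contexts were higher in paternal-7 arrays, blue where none was. Bars on the labelled points are standard errors, and the Snhg14 probe sets stand at 2.17, 3.41 and 4.42.

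The other imprinted genes fixed in advance on both chromosomes gave no call. Only the proximal parts of chromosomes 7 and 15 were duplicated, and the labels do not give the breakpoints. Genes outside these parts, such as those of distal chromosome 7, do not test parent of origin here. Whether the chromosome 15 genes lie inside was not established. Of the maternally expressed genes of proximal chromosome 7, Atp10a stood at -0.13 ± 0.16 and Zim2 at -0.41 ± 0.33, and their list with Ube3a had a camera adjusted p of 0.771. These probe sets were dim, with highest signals of 435 units for Atp10a and 350 for Zim2, so small differences say little about them. Among the 7 measured neighbours on chromosome 7 held to be expressed from both copies, Trpm1 had the largest difference, 0.93 ± 0.26, and was higher in 4 of 4 contexts (adjusted p = 0.535, and 0.0657 adjusted over the list alone). Gabra5 stood at 0.15 ± 0.15, Otud7a at 0.14 ± 0.17 and Chrna7 at -0.06 ± 0.14. Pairs of probe sets gave 0.16 ± 0.15 and -0.75 ± 0.37 for Nipa1, -0.09 ± 0.17 and 0.55 ± 0.24 for Gabrg3, and 0.03 ± 0.15 and -0.56 ± 0.31 for Fam189a1, and the list was not called (adjusted p = 0.354). On distal chromosome 7, Inpp5f stood at -0.11 ± 0.15, Kcnq1ot1 at 0.22 ± 0.59 and Tspan32 at 0.54 ± 0.22 (list adjusted p = 0.654). Peg3 was too dim to test. One of its probe sets was higher in 4 of 4 paternal-7 arrays by a mean log2 difference of 0.83 ± 0.71 (SD over 4 contexts), with a paternal-7 signal of 199.9 ± 86.6 units that exceeded the array median at 15.5 dpc alone. An exact two-sided sign-flip test over 4 pairs cannot reach the threshold. On chromosome 15, the 3 probe sets of Ago2 differed by 0.14 ± 0.13, 0.09 ± 0.16 and 0.05 ± 0.16, those of Trappc9 by -0.15 ± 0.14 and 0.23 ± 0.59, and Chrac1 by -0.18 ± 0.19, with 0 of 3 genes called and a list adjusted p of 0.679. Imprinted genes of other chromosomes were not called either, with list adjusted p-values of 0.584 for the 5 paternally and 0.532 for the 10 maternally expressed genes. Among the 200 probe sets with the smallest p, 19 of the 147 with a known chromosome lay on chromosome 7. That is 12.9% against 7.28% of all tested probe sets (Fisher's exact test, p = 0.0148, adjusted p = 0.312), while chromosome 15 held 6 of them.

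Outside chromosome 7 no gene passed the test for the duplications, and the largest values that kept 1 sign in all 4 contexts are given as values. Stk36, a kinase of ciliated cells, stood at 1.26 ± 0.27, Mybpc1 at 1.21 ± 0.30, Ttpal at 1.09 ± 0.28 (at least 1.63-fold) and Kcnj5 at 1.07 ± 0.27. Gm9999 of chromosome 7 stood at 1.08 ± 0.18. At the other end, Pi4kb stood at -1.46 ± 0.26 (at least 1.79-fold), Pisd-ps3 at -1.25 ± 0.20, Gjc1 at -1.24 ± 0.28, Zfp618 at -1.23 ± 0.35, and one probe set of Camk2a at -1.18 ± 0.32. Adjusted p-values of these genes were 0.532 or 0.535. Each value is that of a single probe set, and of most of these genes other tested probe sets did not share it. They stood at -0.14 ± 0.14 for Stk36, 0.03 ± 0.14 for Gm9999, -0.02 ± 0.14 for Pi4kb, and 0.02 ± 0.13 and -0.19 ± 0.15 for Mybpc1. The 3 others of Ttpal ran from -0.12 to 0.15 and those of Zfp618 from -0.13 to 0.06, and those of Camk2a lay above 0 (0.60 ± 0.17 in the brightest). The other one of Pisd-ps3 stood at -1.24 ± 0.25, and Kcnj5 and Gjc1 had none. Agreement in sign was itself frequent, since 828 of 9666 probe sets outside the Ube3a to Peg12 stretch were higher in all 4 paternal-7 arrays. That is 8.57%, where chance in 4 independent pairs gives 6.25%. The pairs were not independent, since their differences correlated at 0.242 for cortex and cerebellum and at 0.217 for the embryonic ages.

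Of 26 gene lists, 4 were lower in paternal-7 arrays as sets, though no member passed the test alone over all probe sets. RNA-binding and splicing genes had a median log2 difference of -0.26, with 2 of 18 above 0 (camera adjusted p = 0.00474, and adjusted p = 0.697 with an estimated correlation). Sf3b1, a splicing factor, stood at -0.66 ± 0.18 and Neat1, a nuclear noncoding RNA, at 0.50 ± 0.13. Choroid plexus markers had a median of -0.39 with 0 of 5 above 0 (adjusted p = 0.0103, and adjusted p = 0.697 with an estimated correlation). Among them Kcnj13 stood at -0.39 ± 0.13 and Ttr, the transthyretin gene, at -0.22 ± 0.16. Cerebellum markers (median -0.26, 1 of 10 above 0, adjusted p = 0.0262, and adjusted p = 0.778 with an estimated correlation) included Zic1 at -0.60 ± 0.16 and Lhx9 at -0.91 ± 0.26, which were called adjusted over the list alone (2 genes). Neural progenitor markers (median -0.20, 1 of 8 above 0, adjusted p = 0.0262, and adjusted p = 0.697 with an estimated correlation) included Rfx4 at -0.55 ± 0.16. In each of the other 3 lists the count adjusted over the list alone was 0. The pair differences spread more in the embryonic contexts, with an SD over probe sets of 0.576 at 15.5 dpc and 0.531 at 13.5 dpc against 0.399 in cortex and 0.416 in cerebellum. With both embryonic pairs left out, the adjusted p-values were 0.101 for RNA-binding genes, 0.252 for choroid plexus, 0.445 for cerebellum and 0.359 for progenitor markers, so that these calls ended, and 2 other lists were called higher, synapse genes (adjusted p = 0.00109) and monoamine genes (adjusted p = 0.0454). Without the 15.5 dpc pair alone, 1 list was called in place of 4. Markers of oligodendrocytes, microglia, endothelium, meninges, hypothalamic peptides, and genes of hypoxia, glucocorticoid response and the unfolded protein response were called in none of the comparisons, with adjusted p-values for the duplications between 0.354 and 0.988.

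Within each context the duplications could be compared only as single arrays, with no test. At least 2-fold differences on the log2 scale, among probe sets above the 75th percentile on either array, numbered 91 in cortex, 81 in cerebellum, 246 at 15.5 dpc and 209 at 13.5 dpc. Between tissues of 1 duplication the counts were 172 and 240 for cortex against cerebellum and 682 and 907 for 15.5 against 13.5 dpc. Snhg14 had the largest log2 difference above 0 in each of the 4 contexts among probe sets with a single gene name. At 13.5 dpc this order rests on maternal-7 signals below the array median. There Snhg14 read 667 against 33.9 signal units and Susd5, the next, 1101 against 102. Zfp575, a zinc finger gene of chromosome 7, read 703 signal units in the paternal-7 and 111 in the maternal-7 cerebellum and was higher in 4 of 4 contexts. Ckm, the muscle creatine kinase gene, also of chromosome 7, read 722 against 133 in cortex and was higher in 4 of 4 contexts. Piezo1, a mechanosensitive channel, read 209.7 against 905 in cortex and 242 against 1113 in cerebellum. Fam193a read 39.5 against 907 in cerebellum and 933 against 111 at 13.5 dpc, in opposite directions. In the embryonic pairs, one probe set of Meg3 read 211 against 1951 at 15.5 dpc and one of Sox11 1529 against 12606 at 13.5 dpc, while other probe sets of these genes differed less. No probe set differed in its duplication effect between neonatal and embryonic contexts (limma, 0 called, smallest adjusted p = 0.440, 1209 at an unadjusted p under 0.05). In simulated data this test recovered 3.28% of effects of 2 log2 units, so that smaller differences were not detectable with 8 arrays.

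Among the largest called differences between neonatal cortex and cerebellum were several transcription factor genes and genes of transmitter systems, a grouping read from the genes themselves and not tested as a set. In cortex, Zbtb20, a transcriptional repressor of the developing forebrain, was higher by 3.40 ± 0.26 log2 units (limma adjusted p = 0.00983, at least 8.13-fold), reading 1890.4 ± 64.2 against 126 ± 15.0 signal units (SD, n = 2 arrays each). The receptor tyrosine kinase gene Met was higher by 3.25 ± 0.26 (at least 3.44-fold), the dopamine receptor gene Drd1 by 2.99 ± 0.31 (at least 2.61-fold), the vesicular glutamate transporter gene Slc17a7 by 2.34 ± 0.26, and the deep-layer factor Bcl11b by 2.05 ± 0.22. Kcnip2, Gda, Egr3, Vax1, Zeb2, Pmch and Bcl11a were higher by 2.09 to 2.56. In cerebellum, the transcription factor gene Tfap2b was higher, with a log2 difference of -4.10 ± 0.32 (cortex minus cerebellum, adjusted p = 0.00983) and 6976 ± 476 against 351 ± 17.1 signal units. One probe set of Slc6a2, the noradrenaline transporter gene, was higher there at -3.84 ± 0.25 (at least 5.02-fold), but 2 other probe sets of this gene were not called (0.12 ± 0.28 in the brightest, and -0.60 ± 0.29). Also higher was Tph2, which encodes the enzyme of serotonin synthesis in neurons, at -2.64 ± 0.19 (at least 2.88-fold). Pax7, a factor of the dorsal midbrain and neural tube, stood at -3.86 ± 0.37 (at least 4.84-fold), Pou4f1 at -2.45 ± 0.20 (at least 3.88-fold) and Shox2 at -2.39 ± 0.25, and Cnpy1, C1ql2, Hcrtr1, Rassf4, Cpne9 and Lgi3 lay between -2.84 and -1.68. The sample titles do not give the limits of the dissections, and which cells gave the signals of the genes named for either region was not tested. Other tested probe sets of some of these genes differed less. For Zbtb20, 2 of the 5 others were called (1.89 ± 0.19 and 1.74 ± 0.21) and 3 were not (0.75 to 1.26). No other tested probe set of Zeb2, Bcl11a, Pou4f1, Rassf4 or Lgi3 was called. The smallest differences among those of Zeb2 and Bcl11a were 0.56 ± 0.25 and 0.65 ± 0.32. Another of Bcl11a stood at 1.97 ± 0.28, close to the named one. The only others of Pou4f1, Rassf4 and Lgi3 stood at -1.44 ± 0.24, -0.58 ± 0.21 and -0.74 ± 0.27.

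Of the 14 measured cortex markers 2 rose, Neurod2 (1.64 ± 0.19) and Bcl11b (1.91 ± 0.23 in its brightest probe set), and 13 lay above 0. Adjusted over the list alone, 7 rose and 1 fell, and camera called the list (adjusted p = 1.87e-08, and adjusted p = 0.250 with an estimated correlation). Cerebellum markers were called lower in cortex (median -0.33, adjusted p = 0.00315, and adjusted p = 0.697 with an estimated correlation). Only Tfap2b of the 10 passed the test over all probe sets, and 2 adjusted over the list alone. Monoamine genes were called lower (median -0.48, adjusted p = 0.00216, and adjusted p = 0.507 with an estimated correlation), with Tph2 lower and Drd1 higher in cortex, and 3 lower and 1 higher adjusted over the list alone. Dbh, the enzyme that makes noradrenaline, stood at -1.41 ± 0.21 (adjusted p = 0.0668). The 3 measured immediate early genes were called higher (adjusted p = 1.81e-05, and adjusted p = 0.250 with an estimated correlation), with Egr3 at 2.42 ± 0.29, 3 genes called adjusted over the list alone, and Nr4a3 at 3.23 ± 0.47 (adjusted p = 0.0666). RNA-binding genes were called higher (median 0.13, adjusted p = 0.00315, and adjusted p = 0.507 with an estimated correlation), with Celf2 the member of smallest p (adjusted p = 0.166) and 0 of 18 past the test (2 adjusted over the list alone). In all, 26 probe sets were higher in cortex and 17 in cerebellum. Without the maternal-7 or the paternal-7 array of cortex, and without either array of cerebellum, limma called 0 probe sets in place of 43, with the lone array assumed to vary like the others. Without the 15.5 dpc pair it called 21 and without the 13.5 dpc pair 20.

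**Figure D3:**
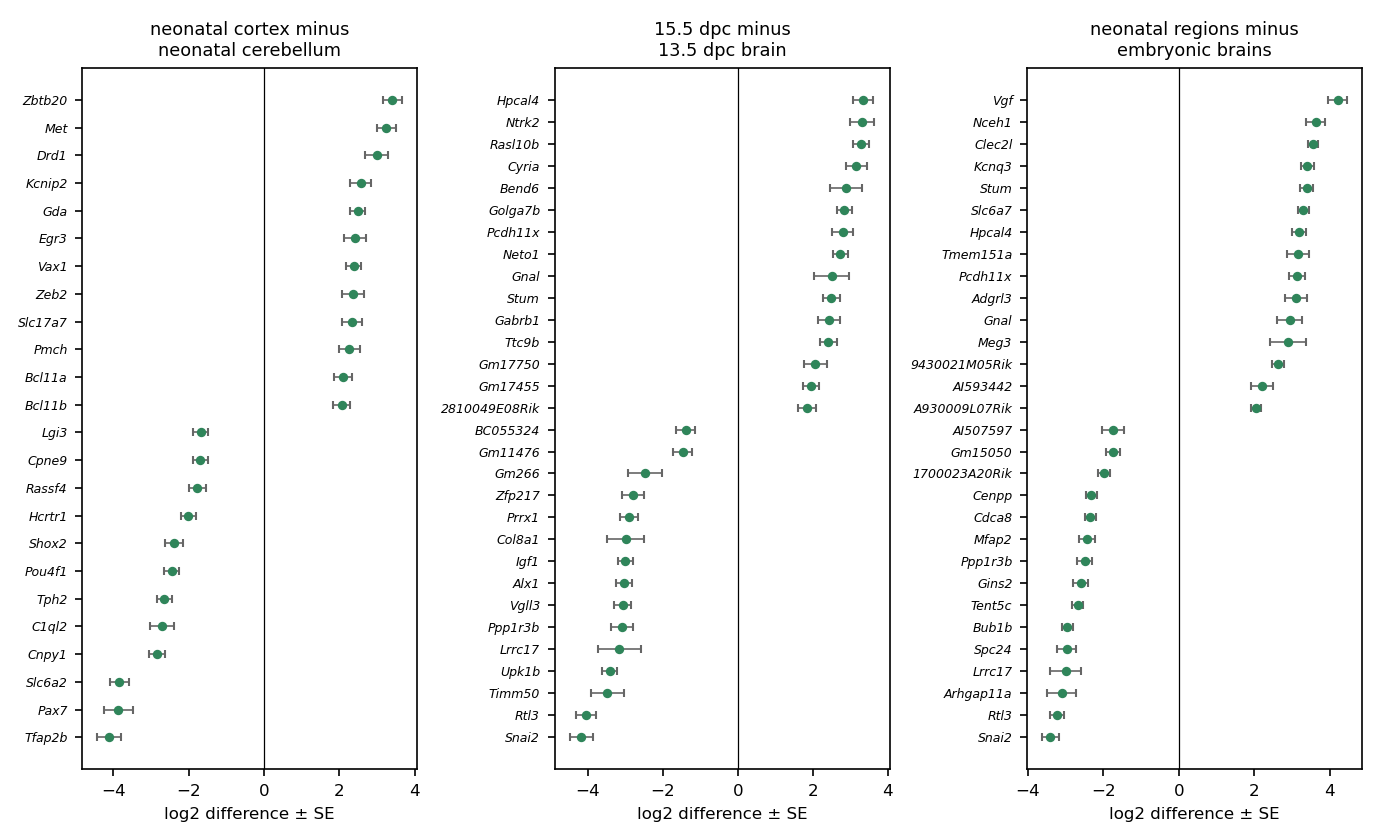
Log2 differences with standard errors (limma, horizontal axes) of the genes with the largest called differences in the 3 comparisons between contexts. Tfap2b stands at -4.10 for cortex minus cerebellum, Snai2 at -4.17 for 15.5 minus 13.5 dpc and Vgf at 4.21 for neonatal minus embryonic tissue before the median of all probe sets is taken off.

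Between 13.5 and 15.5 dpc, the list of synapse genes was called higher and that of cell cycle genes lower at camera's preset correlation, and neither was called with an estimated correlation (adjusted p = 0.435 for both). The neurotrophin receptor gene Ntrk2 rose by 3.32 ± 0.33 log2 units (limma adjusted p = 0.00923, at least 9.19-fold), from 202 ± 51.6 to 2518 ± 260 signal units (SD, n = 2 arrays each). The neuronal calcium sensor gene Hpcal4 rose by 3.34 ± 0.26 (at least 3.88-fold), Rasl10b by 3.29 ± 0.22 (at least 9.91-fold), Neto1, an auxiliary subunit of glutamate receptors, by 2.74 ± 0.19 (at least 1.95-fold), and Gabrb1, a receptor subunit for GABA, by 2.43 ± 0.29 (at least 1.35-fold). Cyria, Bend6, Golga7b, Pcdh11x, Gnal, Stum and Ttc9b rose by 2.41 to 3.16. Gnal stood at 1.64 ± 0.31 and was no longer called without the paternal-7 array of 13.5 dpc. Other tested probe sets of some of these genes differed less. Of the 4 others of Ntrk2, 1 was called (1.52 ± 0.28) and 3 were not (-0.13 to 0.88). The only other tested probe sets of Bend6 (0.70 ± 0.18), Golga7b (0.41 ± 0.19) and Gabrb1 (0.64 ± 0.21) were not called, nor was one of those of Gnal (-0.07 ± 0.24). Of the 43 measured genes of synapse maturation 16 rose and 0 fell (camera adjusted p = 5.17e-12, and adjusted p = 0.435 with an estimated correlation), among them the glutamate receptor gene Grm5 by 2.10 ± 0.21 and the synaptic vesicle gene Syn2 by 1.80 ± 0.17. Adjusted over the list alone, 28 rose and 1 fell. Of the 14 cortex markers 2 rose, Neurod2 by 1.45 ± 0.19 and Camk2a by 1.13 ± 0.24 in its brightest probe set, and 7 adjusted over the list alone (adjusted p = 0.00641, and adjusted p = 0.435 with an estimated correlation).

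The largest fall was that of Snai2, a transcription factor of neural crest and mesenchyme, which stood at -4.17 ± 0.31 (15.5 minus 13.5 dpc, adjusted p = 0.00482) with 5761 ± 866 signal units at 13.5 dpc and 277 ± 141 at 15.5 dpc. The craniofacial mesenchyme factors Alx1 and Prrx1 stood at -3.03 ± 0.22 (at least 4.06-fold) and -2.90 ± 0.23, the epithelial gene Upk1b at -3.42 ± 0.20 (at least 3.80-fold), and the growth factor gene Igf1 at -3.00 ± 0.20. Rtl3, Timm50, Lrrc17, Ppp1r3b, Vgll3, Col8a1 and Zfp217 lay between -4.05 and -2.80. The other tested probe set of Timm50 stood at -0.19 ± 0.20, and of the 3 others of Upk1b 1 was not called (-0.88 ± 0.27). Of the 6 measured meninges and mesenchyme genes 2 fell, Prrx1 and Thbs2 (-1.69 ± 0.32), and the list was not called (adjusted p = 0.114). Of the 16 cell cycle genes 5 fell and 0 rose (adjusted p = 2.87e-04, and adjusted p = 0.435 with an estimated correlation), among them the mitotic gene Dlgap5 (-1.85 ± 0.21) and Ccne1, a cyclin gene (-1.39 ± 0.21), and 9 fell adjusted over the list alone. In all 465 probe sets rose and 406 fell, 871 together. Without the paternal-7 array of 13.5 dpc limma called 0 probe sets and without the maternal-7 array of 13.5 dpc 522. Without the cortex or the cerebellum pair limma called 104 and 123. The differences themselves do not change in these 2 fits, since the neonatal arrays do not enter them, and only the error does. All 871 also kept their sign without any single array of 15.5 or 13.5 dpc. That says little, since a call already needs similar differences in both duplications.

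Neonatal cortex and cerebellum together stood above the embryonic brains in the lists of synapse and astrocyte genes and below them in the list of cell cycle genes at camera's preset correlation. None of these lists was called with an estimated correlation (adjusted p = 0.399 for each), a setting that rests on 3 residual degrees of freedom. The neonatal samples were cortex and cerebellum and the embryonic ones brain, so stage cannot be told apart from region. Here and in the next paragraph, genes that rose or fell are those called higher or lower in neonatal tissue. The median of all probe sets lay at -0.155, and centring the arrays moved it to 0.02, so values are given relative to that median. Adjusted p-values, calls and bounds are those of the comparison before the median is taken off. Vgf, a neuropeptide precursor gene, was higher by 4.36 ± 0.24 (limma adjusted p = 5.74e-04), reading 3924 ± 696 against 199.6 ± 191 signal units (SD, n = 4 arrays each). Kcnq3, a potassium channel gene, was higher by 3.56 ± 0.17 (at least 6.50-fold), Clec2l by 3.70 ± 0.13 (at least 7.28-fold), Nceh1 by 3.78 ± 0.25 (at least 4.18-fold) and the proline transporter gene Slc6a7 by 3.46 ± 0.15. Stum, Hpcal4, Tmem151a, Pcdh11x, Adgrl3 and Gnal were higher by 3.09 to 3.54. Meg3, a maternally expressed noncoding RNA, was higher by 3.06 ± 0.47 in one probe set and by 1.02 ± 0.13 in another. Lower in neonatal tissue were Snai2 (-3.25 ± 0.22, at least 5.23-fold), Rtl3 (-3.07 ± 0.19, at least 4.12-fold), and the cell division genes Bub1b (-2.80 ± 0.15, at least 4.70-fold), Spc24 (-2.81 ± 0.25, at least 5.34-fold) and Gins2 (-2.44 ± 0.20). Arhgap11a, Lrrc17, Tent5c, Ppp1r3b, Mfap2, Cdca8 and Cenpp lay between -2.95 and -2.16. Several of these differences rested largely on the 13.5 dpc arrays. Without that pair, again relative to the median, Snai2 stood at -1.20, Rtl3 at -1.09, Lrrc17 at -1.31, Tent5c at -1.26 and Ppp1r3b at -0.84, and Lrrc17 and Ppp1r3b were no longer called. Stum then stood at 2.25, Pcdh11x at 1.85, Gnal at 1.79 and Hpcal4 at 1.64. Without the 15.5 dpc pair Snai2 stood at -5.30, Rtl3 at -5.06, Lrrc17 at -4.39, Ppp1r3b at -3.85, Tent5c at -3.79 and Hpcal4 at 5.05. Before the median is taken off, the only other tested probe set of Kcnq3 (0.29 ± 0.15) and one of those of Gnal (-0.35 ± 0.17) were not called. Nor was 1 of the 5 others of Adgrl3 (0.19 ± 0.14). The other 4 of Adgrl3 were called at 0.54 to 1.14, both others of Nceh1 at no more than 2.10 ± 0.35, and the other one of Cenpp at -1.09 ± 0.17.

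Of the 43 synapse genes 33 rose and 0 fell, with a median of 1.44 relative to all probe sets (camera adjusted p = 1.97e-15, and adjusted p = 0.399 with an estimated correlation), and 35 rose and 1 fell adjusted over the list alone. Grm5 was higher by 2.97 ± 0.15 and the sodium channel gene Scn2a by 2.66 ± 0.20. All 4 measured astrocyte genes rose, also adjusted over the list alone, Slc4a4 by 1.64 ± 0.12, the glutamate transporter genes Slc1a3 and Slc1a2 by 1.30 ± 0.15 and 1.28 ± 0.16, and the water channel gene Aqp4 by 1.19 ± 0.25 (list adjusted p = 0.00269, and adjusted p = 0.399 with an estimated correlation). Of the 39 axon guidance genes 16 rose and 4 fell (adjusted p = 9.69e-04, and adjusted p = 0.399 with an estimated correlation; 19 rose and 5 fell adjusted over the list alone), with Pcdh17 at 2.27 ± 0.13 and Epha3 at -1.22 ± 0.13. This split moved with the scaling, to 21 rising and 1 falling with centred arrays and to 13 and 2 with quantile normalization. Of the 12 monoamine genes 5 rose, also adjusted over the list alone, among them the serotonin receptor genes Htr1b (1.39 ± 0.13) and Htr2c (1.33 ± 0.18), at a list adjusted p of 0.00557 and an adjusted p of 0.399 with an estimated correlation. Others of the 5 rested on 1 region. Drd1 went from 1.24 to 0.05 without the cortex pair. Without the cerebellum pair Slc18a2 went from 1.05 to 0.44, and Tph2 from 0.65 to -0.67, a reversed sign. Of the 16 cell cycle genes 11 fell and 1 rose (adjusted p = 9.69e-04, and adjusted p = 0.399 with an estimated correlation), the counts adjusted over the list alone were the same, and with centred arrays 8 fell and 1 rose. Of the 14 Wnt and Shh patterning genes 3 fell, Rspo2 (-1.78 ± 0.32), Sfrp1 (-0.77 ± 0.17) and Gli3 (-0.70 ± 0.13), at an adjusted p of 0.0360 and an adjusted p of 0.399 with an estimated correlation, and 7 fell adjusted over the list alone. Over all 13221 probe sets, 1887 were called higher and 2168 lower, so that 46.5% of 4055 were higher, against 69.4% of 3456 with centred arrays. Without the 13.5 dpc pair Grm5 stood at 1.88, Htr2c at 0.67 and Gli3 at -0.28, the last 2 no longer called, and without the 15.5 dpc pair Gli3 stood at -1.12. Several cell cycle and synapse genes also rested on the 13.5 dpc pair. Without it Dlgap5 went from -0.96 to -0.08, Ccne1 from -0.79 to -0.14 and Gad2 from 1.43 to 0.64, none still called. Others kept their call, such as Syn2 at 1.22. Epha3 stood at -0.51 without the cerebellum pair, no longer called, and at -1.93 without the cortex pair. Without the 13.5 dpc pair limma called 1104, without the cortex pair 1816 and without the cerebellum pair 1922.

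**Figure D4:**
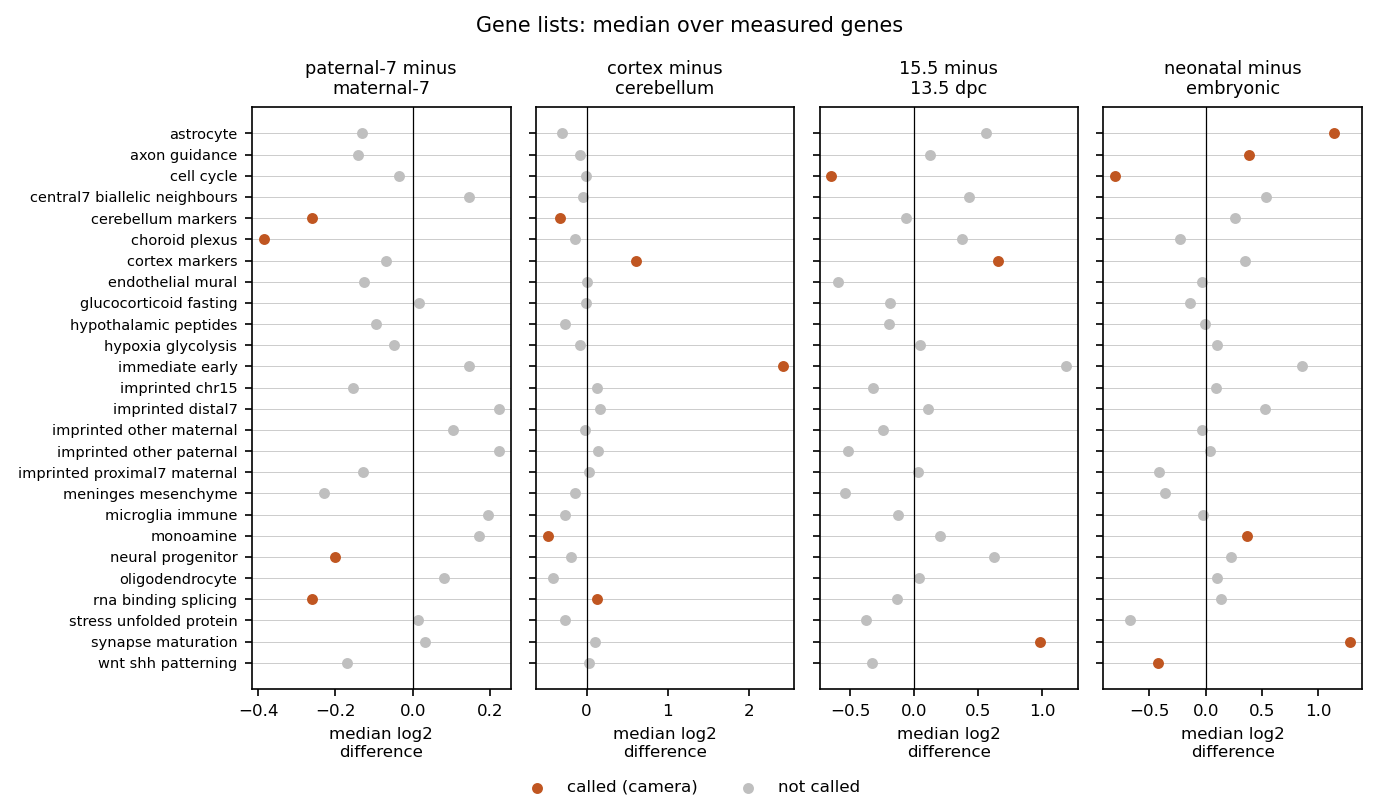
Median log2 difference over the measured genes of each of the 26 tested gene lists in the 4 comparisons (horizontal axes, before the median of all probe sets is taken off), with lists called by camera at its preset correlation in orange. The synapse list stands at 1.28 and the cell cycle list at -0.80 for neonatal minus embryonic tissue.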

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

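The tests of a mislabelled array, of a single misbehaving probe set, of array scaling, of a single array standing apart and of the 3' to 5' ratios were chosen after the results were seen. Every group held 1 array, so no array could be tested as an outlier within a group. Some control probe sets, which enter no comparison, differed with the duplications in both contexts of a stage by at least 0.8 log2 units. Only the higher signal of each pair had to exceed the array medians. The 3' control probe set of the transferrin receptor was lower in paternal-7 neonates, with a log2 difference of -0.87 in cortex (525 against 1007 signal units) and -1.03 in cerebellum (449 against 978). In embryos it went the other way, by 0.95 at 15.5 dpc and 0.22 at 13.5 dpc. The 5' and middle probe sets of this gene were also lower in paternal-7 neonates, by -0.63 and -0.56 in cortex and -0.44 and -0.51 in cerebellum. At 15.5 and 13.5 dpc the 5' one stood at -0.07 and 0.34 and the middle one at -0.92 and -0.93. The middle one lay below the array median throughout. One middle control probe set of pyruvate carboxylase was lower in paternal-7 embryos, by -1.18 at 15.5 dpc (249 against 640) and -1.05 at 13.5 dpc (209 against 493). Its paternal-7 signals lay below the array medians of 278 and 286, so these sizes are not exact. At 15.5 and 13.5 dpc the other middle probe set differed by -0.32 and -0.40, the 5' one by -0.08 and 0.06 and the 3' one by -0.38 and 0.04.

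Snhg14 was higher with the paternal duplication, and of 4 other tested probe sets from Ube3a to Peg12, none of them called, those of B230209E15Rik and A230006K03Rik were higher in all 4 contexts while those of Ube3a and Ipw were not. For B230209E15Rik this counts embryonic pairs with smaller differences, which may lie near background. Array scaling is argued against, since it moved the difference of the called Snhg14 probe set by at most 1.09%, and so is a single misbehaving probe set, since both other Snhg14 probe sets were higher in 4 of 4 contexts, by at least 9.49 times their SE. A single mislabelled array, which would bring the difference of its pair near 0, is argued against too, since the smallest of the 12 pair differences of the 3 Snhg14 probe sets was 1.53 log2 units, and the SD of pair differences over probe sets was at most 0.576. Only 8 splits of the arrays part all 4 pairs, too few for a share under 0.05; the real split called 1 probe set and the highest other 0. The parent of origin, which the design names, stays open and untested as a hypothesis: B230209E15Rik and A230006K03Rik may be made from the paternal copy.

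At 13.5 dpc, Snai2, Prrx1, Alx1 and Upk1b stood far above 15.5 dpc. A single array standing apart would leave a difference near 0 in 1 duplication. The value closest to 0 of the 4 genes in either duplication was -2.90, with an SD over probe sets of at most 0.729. This cannot decide the question, since the 4 genes were picked as large called falls, and a call already needs similar differences in both duplications. Non-neural tissue in the 13.5 dpc dissection remains a candidate explanation. From a list of 57 other mesenchyme and epithelium markers 6 were measured, with a median log2 difference of -0.62 ± 0.31 (SE), 2 of them falling (Pax9 and Eya1), but the epithelial part rested on Epcam alone (-0.05 ± 0.26), while the brightest, Epcam and Tbx18, read 2339 and 1401 signal units at 13.5 dpc. Because 5 of the 6 also exceeded the median on all 4 neonatal arrays, from cells that no table identifies, such tissue cannot be told apart from a change with age, which the design names and which stays untested.

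Single probe sets, one of Meg3 (-2.90 at 15.5 dpc) and one of Sox11 (-3.00 at 13.5 dpc), were much lower in paternal-7 embryos than other probe sets of the same genes. The paternal-7 signal of this Meg3 probe set, 211, lay below the array median of 278, so its difference is not an exact size. RNA degradation of the kind seen at the 3' and 5' ends is argued against, since 0 of the 4 ratios of Actb and Gapdh on these arrays exceeded those of every other array. Loss of signal in single probe sets cannot be told apart from wider noise: over 2032 genes with at least 2 tested probe sets, the brightest pair disagreed 1.53 times more in the embryonic than in the neonatal pairs, but the spread of all pair differences was also 1.36 times larger there. Different transcript ends in the embryos stay open, untested, as does the difference between the duplications itself.

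For the neonatal against the embryonic contexts, 1 of 34 splits of the 8 arrays, the real one, called as many probe sets as the real one (2614 called in this model, against 1 for the highest other). The arrays of a context resemble each other and only 3 splits keep contexts whole, too few for a share under 0.05. For the gene lists, 9 of 34 splits called at least as many as the 5 of the real split, and the highest other called 8; of the 3 splits that keep contexts whole, the highest other called 5. For the duplications the 8 splits are too few as well, with 4 lists in the real split and 2 in the highest other (1 of 8 splits reached the real count).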

How the results depend on the processing

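The fits without both embryonic pairs, and the gene list tests without each pair, were chosen after seeing the data. Unless stated, the cause of a change was not tested. The duplications gave 1 called probe set, against 0 with a floor of 1 and 0 with no filter, 2 with the larger pseudocount, 2 with no context term, 3 with an intensity trend, 4 with the strict filter and 4 without both embryonic pairs; quantile normalization, median centring and leaving out shared probe sets gave 1. Cortex against cerebellum gave 43, against 22, 93, 11, 83 and 84 with a floor, the larger pseudocount, no filter, the strict filter and an intensity trend, and 15.5 against 13.5 dpc gave 871, against 459, 1324, 207, 1354 and 1409 in the same order. The strict filter tests fewer probe sets. For neonatal against embryonic tissue these settings stayed within 1.5 times of 4055, and the duplication effect differed between stages for 0 probe sets in each (limma; 1209 at an unadjusted p under 0.05 as reported).

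Leaving out 1 pair or array gave 0 to 2 for the duplications, 0 to 21 for cortex against cerebellum, 0 to 522 for 15.5 against 13.5 dpc, 1104 to 4348 for neonatal against embryonic tissue and 0 to 0 for the difference between stages. The gene lists called for the duplications went from 4 to 0 with an estimated correlation, to 2 different lists (synapse and monoamine genes) without both embryonic pairs, and to between 1 and 4 without 1 pair; with an estimated correlation 0 lists were called in the other comparisons too. Chromosome 7 held 1 called probe set, 0 with no filter and 19 of the 200 smallest p, and chromosome 15 held 6 of these. At least 2-fold differences fell to 52, 46, 124 and 106 with the larger pseudocount, and 12, 15, 30 and 30 reached 4-fold (cortex, cerebellum, 15.5 and 13.5 dpc).

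Among genes named for the duplications, signs reversed for 5 probe sets, none called. Fam189a1 went to -0.0073 with median centring and ran from -0.079 to 0.11 over the pairs left out. Ipw ran from -0.10 to 0.59, Trappc9 from -0.56 to 0.77, and 2 of the 3 probe sets of Ago2 from -0.0039 to 0.20 and from -0.049 to 0.20. Among genes named for their size in the comparisons between contexts 0 reversed, while Tph2 of the monoamine list did for neonatal against embryonic tissue. The former follows largely from the naming rule, which asks for all arrays of one side above those of the other, and is no sign of stability. Signal over background limits the dim side of each difference, which is why bounds are given.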

Other observations

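All values here were picked after the data were examined, from gene lists and windows fixed before. In 10 Mb windows of chromosomes 7 and 15, the third of chromosome 7 held 12 of 59 probe sets at an unadjusted p under 0.05 for the duplications, 6 of them higher in paternal-7 arrays (Fisher's exact test, adjusted p = 0.0464). The fourth of chromosome 15 held 8 of 29, 7 of them higher (adjusted p = 0.0464), among them Baalc, Lrp12, Rims2 and Ncald. The window of Snhg14 held 3 of 16 (adjusted p = 0.410).

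Of the imprinted genes of other chromosomes, 1 of 5 paternally and 2 of 10 maternally expressed ones passed the test between 13.5 and 15.5 dpc, where 871 of all 13221 probe sets did, and neither list was called (camera adjusted p = 0.0624 and 0.311). The values of Airn, Klf14 and Mirg fell by 0.99 (limma adjusted p = 0.0370), 1.57 (adjusted p = 0.0170) and 1.17 (adjusted p = 0.0321) on the log2 scale. The stress gene Ddit3 stood at -1.44 ± 0.18 (adjusted p = 0.0151). Of the endothelial genes, Erg stood at -2.04 ± 0.25 (adjusted p = 0.0132) and Mfsd2a, a lipid transporter gene of the blood-brain barrier, at 1.27 ± 0.24 (adjusted p = 0.0324).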
